A study of Mus musculus with 8 samples.

How the data were processed

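RNA of LLC1 cells, a mouse lung carcinoma line, was profiled 4 h after treatment with X-rays. Per the labels, every array held RNA of untreated cells in Cy3 and of irradiated cells in Cy5, with no exchange of the dyes, for single doses of 2 Gy (3 arrays) and 10 Gy (2 arrays) and for 5 fractions of 2 Gy (3 arrays). The third 10 Gy replicate was not analysed here. The labels do not say how far apart the fractions were given, nor whether arrays with 1 replicate number share a culture, so the numbers were not read as pairs.

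Per the file headers, the scanner files hold an intensity for each spot and channel, the mean and the median pixel signal quantified with ImaGene 9.0, not corrected for background, not normalized and not on a log scale. They hold no background column and no flag for signal above background. The meaning of their spot flags is not given, and flagged spots were kept in the analysis as reported. The deposited series matrix holds log2 ratios of Cy5 over Cy3 per probe. Set against loess-normalized ratios of the mean signals of the same array without background correction, its columns gave r over probes of 0.998 to 1.000 and slopes of 0.993 to 0.999, which settled their scale and direction. The image names in the headers placed the 8 arrays on 2 slides of 4.

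Each array held 45220 spots, 153 of them negative controls, and 41174 probes. The mean signals were corrected with normexp (offset 50) on the foreground alone, since no local background was at hand, and normalized by loess within each array with control spots at weight 0 in limma 3.58.1 and R 4.3.3. No scaling between arrays was applied. Spots of a probe were averaged. A probe was kept if its mean signal lay above the median of the negative controls plus 2.6 robust SD in at least 1 channel on at least 2 arrays, which 21685 probes did. Symbols were updated through the RefSeq accessions of the reference gene table: 27810 probes matched a current symbol, which changed the symbol of 1552, 7128 kept the symbol of the array and 6236 had none. The reference table served for names only and no coordinates were used. For each symbol the probe with the highest mean intensity was tested, 13408 genes in all, of which 4975 had more than 1 kept probe. On the arrays, 44.8% to 49.1% of probes were above background in the untreated channel and 34.7% to 47.5% in the irradiated one. The SD of the log2 ratios of all genes was 0.33 to 0.37 on the 2 Gy arrays, 0.43 to 0.45 on the 5x2 Gy arrays and 0.69 and 0.46 on the 10 Gy arrays.

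In limma, 1 mean per regimen was fitted to the 8 arrays, so that all regimens share 1 estimate of the spread of a gene, moderated with eBayes without trend. Regimens were compared with untreated cells (mean log2 ratio against 0) and with each other, and a moderated F test asked for any difference among the 3. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and genes were called at an adjusted p of 0.05, without a minimum fold. A symbol with a signal not above background on 1 side is given as a fold of at least the ratio to the detection level. A dye effect specific to a gene is part of each comparison with untreated cells and cancels between regimens only where it is the same on each array. With slide as a block, the slide term comes from the 10 Gy pair alone: 10 Gy against 2 Gy is then the difference within slide 1, 5x2 Gy against 10 Gy the difference within slide 2, and 5x2 Gy against 2 Gy their sum. Against untreated cells the block leaves the 10 Gy mean as it was. It moves 2 Gy and 5x2 Gy in opposite directions, by a part of the difference between the 10 Gy arrays.

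The comparisons, the tests, 23 gene lists with their members, and the rule for naming genes were fixed before the data were examined. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list, and fry was run as an alternative. Lists with fewer than 5 kept genes are given as values. Of the 60 calls of lists with the preset correlation none held with an estimated correlation. The lists share a few members, the most being 6 between the p53 target and apoptosis lists. Genes were named by rule: in each comparison up to 10 with the largest fold in each direction among those called whose arrays all have the sign of the mean, or whose groups do not overlap between regimens, leaving out predicted and clone names, up to 4 members of a described list with the smallest p, Cdkn1a, Mdm2, Ccng1, Trp53 and Gapdh in every comparison with untreated cells, and, where none passed, the 5 with the smallest p. The text gives a part of those in full. The agreement of regimens was set against 100 simulations with no effect in which same-numbered arrays were assumed to share 50% of their variance.

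The alternatives were no background correction, normexp with offset 0, median centring without loess, scaling between arrays, the series matrix values, no filter or a stricter one (13116 probes above background in both channels on all arrays), every probe on its own, the mean of the probes of a gene, eBayes with trend and robust, array weights, only the arrays of the groups compared, a replicate block, a minimum of 1.5-fold, and leaving out each array. Slide as a fixed block was planned for the counts of genes. Chosen after seeing the data were the filter from negative controls, slide as a fixed block for the gene lists, slide as a random block, and leaving out spots with an ImaGene flag. The fit was tested on simulated data with 200 changed genes, independent noise, 1 pooled spread per gene for all regimens and no slide effect. Of the changes of 1 on the log2 scale it recovered 100% for 2 Gy and 5x2 Gy and 91.0% for 10 Gy against untreated cells, and 71.6%, 85.1% and 77.6% for 10 Gy against 2 Gy, 5x2 Gy against 2 Gy and 5x2 Gy against 10 Gy. Of the changes of 0.5 it recovered 43.3%, 26.9% and 47.8% against untreated cells and at most 4.48% between regimens. The arrays of 10 Gy differed more from each other (r = 0.427) than those of 2 Gy or 5x2 Gy, so recovery with 10 Gy may be lower on these arrays. Probes without a symbol were tested apart from the genes, and control spots were left out.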

Results

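Gene expression was measured in LLC1 cells, a cell line from a mouse Lewis lung carcinoma, 4 h after treatment with X-rays. Each of the 8 dual-colour oligonucleotide arrays compared irradiated cells (Cy5) with untreated cells (Cy3). The regimens were a single dose of 2 Gy (3 arrays), a single dose of 10 Gy (2 arrays) and 5 fractions of 2 Gy (3 arrays, written 5x2 Gy), which add up to 10 Gy. The labels count 3 biological replicates per regimen, and the third of 10 Gy was not analysed here. An array held 45220 spots, and 13408 genes with a symbol had a probe above background. Between 34.7% and 49.1% of the probes were above background per array and channel, and the number of arrays limits the precision. The arrays lay on 2 slides. Slide 1 held the 2 Gy arrays and 10 Gy replicate 1, and slide 2 held 10 Gy replicate 2 and the 5x2 Gy arrays, so no slide held both 2 Gy and 5x2 Gy. Over all genes, which are not independent replicates, the log2 ratios of the 2 Gy arrays correlated with each other at r = 0.651 to 0.813 and those of the 5x2 Gy arrays at r = 0.829 to 0.886. The 10 Gy arrays correlated with each other at r = 0.427, and 10 Gy replicate 2 correlated with the 5x2 Gy arrays of its slide at r = 0.748 to 0.854. Values below are mean log2 ratios of irradiated over untreated cells ± SE from limma, unless stated. Every gene named for its fold had the sign of the mean on each array of its regimen, or no overlap between the regimens compared.

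The first question was what a single dose of 2 Gy changed against untreated cells. Of the p53 target list 17 of 41 genes rose and of the ribosomal proteins 31 of 77, and of the DNA replication genes 16 of 56 fell, while most members of each list did not pass the test. Dcxr, which encodes L-xylulose reductase and stands on the p53 target list, rose by 2.00 ± 0.17 (4.01-fold, n = 3, adjusted p = 0.00046). Trp53inp1, a p53-induced stress protein, rose by 1.52 ± 0.21 (adjusted p = 0.0026), and Ccng1, the p53 target cyclin G1, by 1.12 ± 0.16 (adjusted p = 0.0028). Cdkn1a, the cell cycle inhibitor p21, was at 0.88 ± 0.32 and did not pass the test (adjusted p = 0.088), and neither did Mdm2, the ubiquitin ligase of p53 (0.48 ± 0.24, adjusted p = 0.18), nor Trp53 itself (0.11 ± 0.11, adjusted p = 0.52). The SE of these genes come from a spread shared by all regimens, not from the 2 Gy arrays alone. Not passing the test thus does not show that they were unchanged. Gapdh, often used as a reference gene, was higher by 0.38 ± 0.10 (adjusted p = 0.025). Outside the lists, Ass1 (argininosuccinate synthase, 1.63 ± 0.23), Crip2 (a LIM domain protein, 1.76 ± 0.29), Pnrc1 (1.41 ± 0.13) and Blnk (1.38 ± 0.10) rose. The lowest values were those of Amh, the anti-Müllerian hormone (-2.96 ± 0.09), and Ttbk1, tau tubulin kinase 1 (-2.88 ± 0.10). Pinlyp fell at least 2.76-fold, to below background in irradiated cells, and the transcription factor Klf2 fell by 1.47 ± 0.11. Vash2 was at -1.66 ± 0.08, but the other probe of Vash2 had the opposite sign.

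Of 41 measured p53 target genes, 17 rose after 2 Gy, 1 fell and 23 did not pass the test, with a list median of 0.56 (limma camera, adjusted p = 3.3e-08, and adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, 21 rose and 1 fell. Of 56 G1/S and DNA replication genes, none rose and 16 fell (19 adjusted over the list alone), with a median of -0.25, and of -0.01 with median centring (adjusted p = 2.2e-07, and adjusted p = 0.46 with an estimated correlation). Examples are Ung, the uracil-DNA glycosylase (-1.01 ± 0.13), Chaf1b, a chromatin assembly factor subunit (-0.56 ± 0.09), and Mcm2 of the replicative helicase (-0.52 ± 0.10). Of 77 ribosomal protein genes, 31 rose and 1 fell (42 and 1 adjusted over the list alone), with a median of 0.50 (adjusted p = 5.7e-12, and adjusted p = 0.46 with an estimated correlation). Of these 77, 61 had a saturated spot, which leaves their ratios inexact, and with median centring their median was 1.12. Of 24 MHC class I presentation genes, 6 rose and none fell (7 adjusted over the list alone), with a median of 0.27, and of 0.55 with median centring (adjusted p = 7.6e-05, and adjusted p = 0.46 with an estimated correlation). H2-L (0.76 ± 0.13) and the TAP-binding protein homologue Tapbpl (0.50 ± 0.09) are examples. Among 26 type I interferon response genes, 6 rose (10 adjusted over the list alone), among them Irgm1 (0.63 ± 0.09), Ifi35 (0.76 ± 0.11) and Ifitm3 (0.76 ± 0.12), with a median of 0.32 (adjusted p = 0.0058, and adjusted p = 0.46 with an estimated correlation). The interferon call ended with median centring, at a median of 0.35 (adjusted p = 0.21). In the fry test it held (adjusted p = 0.042). The calls of p53 targets, G1/S and DNA replication, ribosomal proteins and MHC class I presentation ended there (adjusted p = 0.056 for each).

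In limma, 1207 genes were higher and 1065 lower after 2 Gy at an adjusted p under 0.05, 2272 of 13408, and 56 and 29 of them changed at least 2-fold. With each array centred on its median in place of loess, 2969 were higher and 640 lower, and the median of all genes moved to 0.13, so the direction of a small change here depends on the scaling. Gene-specific dye bias is part of every comparison with untreated cells, since no array had the dyes exchanged. The count was 4461 with slide as a block, 21 with slide as a random block, 942, 489 and 408 without 2 Gy replicate 1, 2 or 3, 1450 without 5x2 Gy replicate 3 and 5382 without either 10 Gy array. The slide term is the difference between the 10 Gy arrays carried over to 2 Gy. It is no correction measured on the 2 Gy arrays, which share 1 slide. With the 2 Gy arrays fitted alone, 4818 genes were called. With slide as a block the G2 and mitosis list, at 0.11 without it (adjusted p = 0.13), was at 0.71 (adjusted p = 1.7e-15). A slide block ended the calls of these 5 lists, at medians of 0.06 for p53 targets (adjusted p = 0.79), -0.04 for G1/S and DNA replication (adjusted p = 0.43), 0.05 for ribosomal proteins (adjusted p = 0.42), 0.07 for MHC class I presentation (adjusted p = 0.85) and 0.07 for type I interferon response (adjusted p = 0.79).

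A single dose of 10 Gy was then compared with untreated cells. Of the p53 target genes 34 of 41 rose, and 50 of 58 genes of G2 and mitosis and 21 of 25 of cholesterol synthesis fell. Cdkn1a rose by 2.598 ± 0.39 (6.05-fold, n = 2, adjusted p = 0.0017), Mdm2 by 2.14 ± 0.29 (adjusted p = 0.00099) and Ccng1 by 2.00 ± 0.19 (adjusted p = 0.00036). Trp53 was at -0.03 ± 0.13 (adjusted p = 0.87) and at 0.40 with median centring, and Gapdh was at 0.03 ± 0.12 (adjusted p = 0.85). Pmaip1, the pro-apoptotic protein Noxa, rose by 3.52 ± 0.55 (adjusted p = 0.0019). Gdf15, a secreted stress cytokine, rose by 2.99 ± 0.80 (adjusted p = 0.022), with log2 ratios of 5.45 in replicate 1 and 0.53 in replicate 2. Crip2 had the highest fold among genes above background on both sides (4.42 ± 0.35, 21.4-fold), and Anxa8, an annexin, rose at least 11.3-fold from below background. Cryab, the small heat shock protein alpha B-crystallin, rose by 3.32 ± 0.56, and Ak1, adenylate kinase 1, by 2.69 ± 0.17. Among the genes that fell were Ccna2 and Ccnb1, the cyclins A2 and B1 of S phase and mitosis (-2.38 ± 0.29 and -2.27 ± 0.42), Prc1, a spindle midzone protein (-2.08 ± 0.50), and the stearoyl-CoA desaturase Scd2 (-2.40 ± 0.18). Amh fell at least 4.96-fold, to below background.

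**Figure D1:**
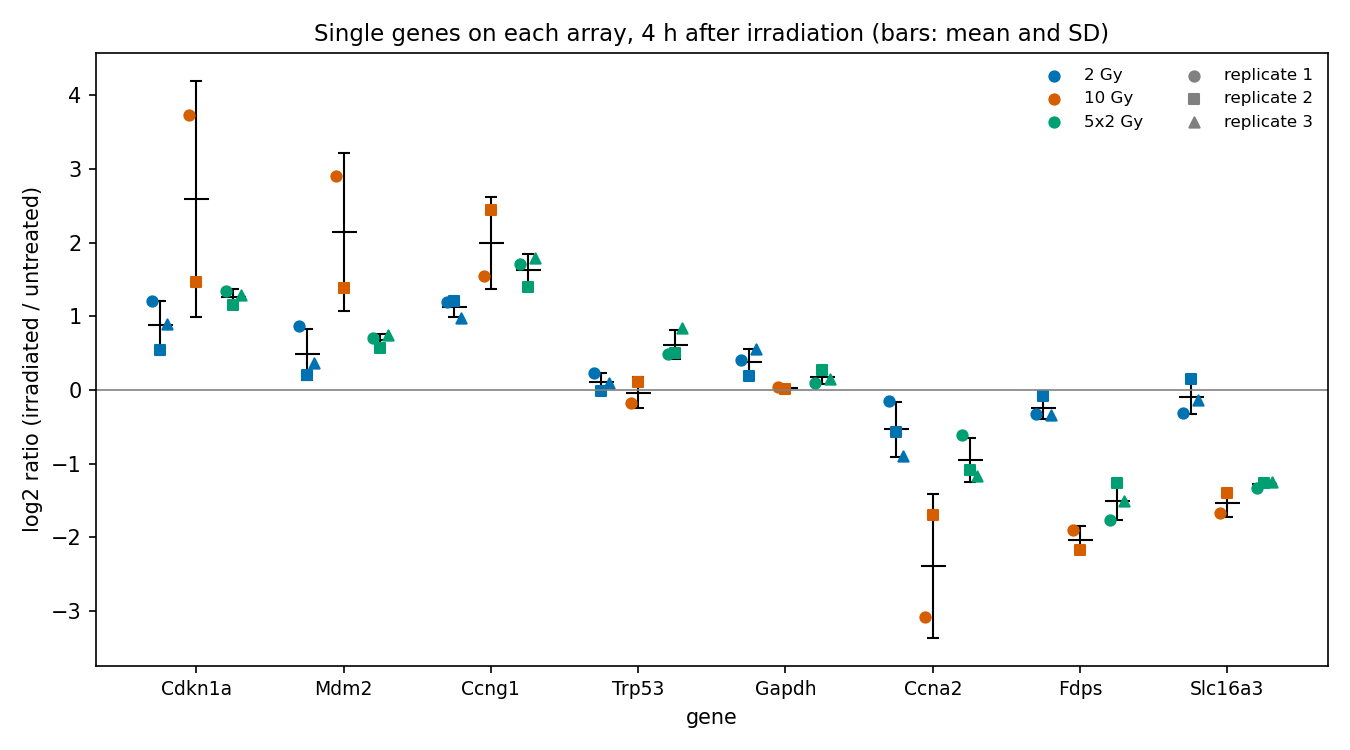
Log2 ratio of irradiated over untreated cells (y axis) of 8 genes (x axis) on each of the 8 arrays. Colours give the regimen, symbols the replicate, and black bars the mean and SD of a regimen. Cdkn1a lies at a mean of 2.598 after 10 Gy with replicate 1 above replicate 2, while Slc16a3 and Fdps lie below 0 on every array of 10 Gy and 5x2 Gy.

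Of the 41 p53 target genes, 34 rose after 10 Gy and none fell (35 and 0 adjusted over the list alone), with a median of 1.37, and of 1.91 in replicate 1 and 1.03 in replicate 2 (adjusted p = 3.9e-20, and adjusted p = 0.26 with an estimated correlation). The death receptor Fas (2.42 ± 0.23) and the pro-apoptotic Bbc3, known as Puma (2.39 ± 0.27), are 2 of those that rose. Of 58 G2 and mitosis genes, 50 fell and 1 rose (52 and 1 adjusted over the list alone), with a median of -1.24, and of -1.80 in replicate 1 and -0.56 in replicate 2 (adjusted p = 3.8e-16, and adjusted p = 0.33 with an estimated correlation). Top2a, the DNA topoisomerase of dividing cells, was at -1.42 ± 0.18. Of 25 cholesterol biosynthesis genes, 21 fell and none rose (22 and 1 adjusted over the list alone), with a median of -1.20, and of -1.34 in replicate 1 and -1.06 in replicate 2 (adjusted p = 1.1e-11, and adjusted p = 0.26 with an estimated correlation). They include Fdps, the farnesyl diphosphate synthase (-2.04 ± 0.14), Msmo1 (-2.10 ± 0.23) and Srebf2, the transcription factor that governs the pathway (-1.59 ± 0.15). Of the 56 G1/S and DNA replication genes, 35 fell and none rose (39 and 1 adjusted over the list alone), with a median of -0.57, and of -0.76 in replicate 1 and -0.28 in replicate 2 (adjusted p = 4.2e-10, and adjusted p = 0.33 with an estimated correlation), Mcm4 at -0.94 ± 0.13. Of the 77 ribosomal protein genes, 45 rose and 1 fell (57 and 2 adjusted over the list alone), with a median of 0.74 (adjusted p = 6.2e-15, and adjusted p = 0.33 with an estimated correlation), such as Rpl32 (1.49 ± 0.16). That list was at 1.18 in replicate 1, 0.24 in replicate 2 and 1.38 with median centring. The 4 mitochondrially encoded transcripts, too few for the list test, had a median of -0.80, and of 0.009 with median centring. It was -1.70 in replicate 1 and 0.008 in replicate 2, and the medians after 2 Gy and 5x2 Gy were -0.10 and 0.25. Of the 4, 3 had a saturated spot, which leaves these ratios inexact. Of 36 hypoxia and glycolysis genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.00079, and adjusted p = 0.46 with an estimated correlation). The lactate transporter Slc16a3 (-1.53 ± 0.13) and the glucose transporter Slc2a1 (-1.68 ± 0.19) fell, while Ddit4, which is also a p53 target, rose by 2.15 ± 0.23. Of the 24 MHC class I presentation genes, 10 rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.42, and of 0.80 with median centring (adjusted p = 1.6e-06, and adjusted p = 0.33 with an estimated correlation), and the peptide transporter Tap1 was at 1.62 ± 0.21. Of 41 homologous recombination and Fanconi anaemia genes, 16 fell and 3 rose (20 and 4 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.00023, and adjusted p = 0.49 with an estimated correlation), among them the checkpoint kinase Chek1 (-1.05 ± 0.12). Of the 26 type I interferon response genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.00023, and adjusted p = 0.33 with an estimated correlation). Without 10 Gy replicate 1 the calls of these 3 lists ended, at medians of 0.22 for MHC class I presentation (adjusted p = 0.055), -0.07 for homologous recombination (adjusted p = 0.40) and 0.35 for interferon response (adjusted p = 0.055).

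In limma, 1663 genes were higher and 2120 lower after 10 Gy, 3783 in all, and 339 and 332 of them changed at least 2-fold. With median centring 2293 were higher and 1616 lower, and the hypoxia and glycolysis list then lost its call (median -0.04, adjusted p = 0.18). The spread of 2 arrays is borrowed from the other regimens, whose arrays differed less from each other. The SE and p-values of limma printed for 10 Gy can thus understate the variation between its 2 arrays. Those printed for the other regimens take in the difference between the 10 Gy arrays. They can overstate the variation among the arrays of those regimens. With array weights, low for both 10 Gy arrays, the count was 222. The count was 6520 with slide as a block, 1466 with slide as a random block, 6080 without 10 Gy replicate 2 and 280 with the 10 Gy arrays fitted alone.

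After 5 fractions of 2 Gy, 23 of 41 p53 target genes were higher than in untreated cells and 1 lower, while 29 of 56 DNA replication genes and 17 of 25 cholesterol synthesis genes were lower, with 1 of the latter higher. The medians of these lists had the same direction on all 3 arrays. Cdkn1a rose by 1.27 ± 0.32 (2.41-fold, n = 3, adjusted p = 0.012), Mdm2 by 0.67 ± 0.24 (adjusted p = 0.044), Ccng1 by 1.64 ± 0.16 (adjusted p = 0.00019) and Trp53 by 0.61 ± 0.11 (adjusted p = 0.0022). Gapdh was at 0.18 ± 0.10 (adjusted p = 0.17). Crip2 (2.85 ± 0.29), Ass1 (2.41 ± 0.23), Dcxr (2.27 ± 0.17) and Ak1 (2.16 ± 0.14) had the highest folds among genes above background on both sides, and Anxa8 rose at least 4.98-fold. Ephx1, the microsomal epoxide hydrolase, rose by 1.93 ± 0.27, and Eif4ebp2, a repressor of translation initiation, by 1.80 ± 0.21. Ttbk1 (-2.53 ± 0.10) and Klf2 (-1.73 ± 0.11) were lower, and Amh fell at least 5.12-fold. Gpt2 and Trib3 were at -1.65 ± 0.36 and -1.54 ± 0.42.

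Of the 41 p53 target genes, 23 rose after 5x2 Gy and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.64 (adjusted p = 8.6e-08, and adjusted p = 0.65 with an estimated correlation). That median was 1.16 with slide as a block, which carries over a part of the difference between the 10 Gy arrays. Sulf2, a heparan sulfatase, rose by 1.68 ± 0.11. Of the 56 G1/S and DNA replication genes, 29 fell and none rose (29 and 0 adjusted over the list alone), with a median of -0.37 (adjusted p = 6e-06, and adjusted p = 0.65 with an estimated correlation), and thymidylate synthase, Tyms, was at -0.99 ± 0.10. Of the 25 cholesterol biosynthesis genes, 17 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.74 (adjusted p = 6e-06, and adjusted p = 0.65 with an estimated correlation). Fdps was at -1.51 ± 0.12 and the lanosterol demethylase Cyp51 at -0.87 ± 0.10. Of the 58 G2 and mitosis genes, 14 fell, none rose and 44 did not pass the test (11 fell adjusted over the list alone), with a median of -0.20 (adjusted p = 0.042, and adjusted p = 0.83 with an estimated correlation). Of the 36 hypoxia and glycolysis genes, 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.024, and adjusted p = 0.81 with an estimated correlation), Slc16a3 at -1.28 ± 0.11 and Pdk1, the pyruvate dehydrogenase kinase, at -1.16 ± 0.14. Of 49 extracellular matrix and TGF-beta response genes, 17 rose and 7 fell (17 and 7 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.037, and adjusted p = 0.65 with an estimated correlation), among them the matricellular Thbs2 (1.15 ± 0.09), Tgfbi (1.41 ± 0.13) and the membrane-bound metalloproteinase Mmp14 (1.02 ± 0.10). Of the 24 MHC class I presentation genes, 8 rose (7 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.017, and adjusted p = 0.81 with an estimated correlation). Of the 26 type I interferon response genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.034, and adjusted p = 0.65 with an estimated correlation). Of the 77 ribosomal protein genes, 3 rose and 3 fell (0 and 2 adjusted over the list alone), with a median of 0.20, and of 0.43 with median centring (adjusted p = 0.016, and adjusted p = 0.83 with an estimated correlation). In the fry test the calls of G2 and mitosis, MHC class I presentation and ribosomal proteins ended (adjusted p = 0.38, 0.088 and 0.42).

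**Figure D2:**
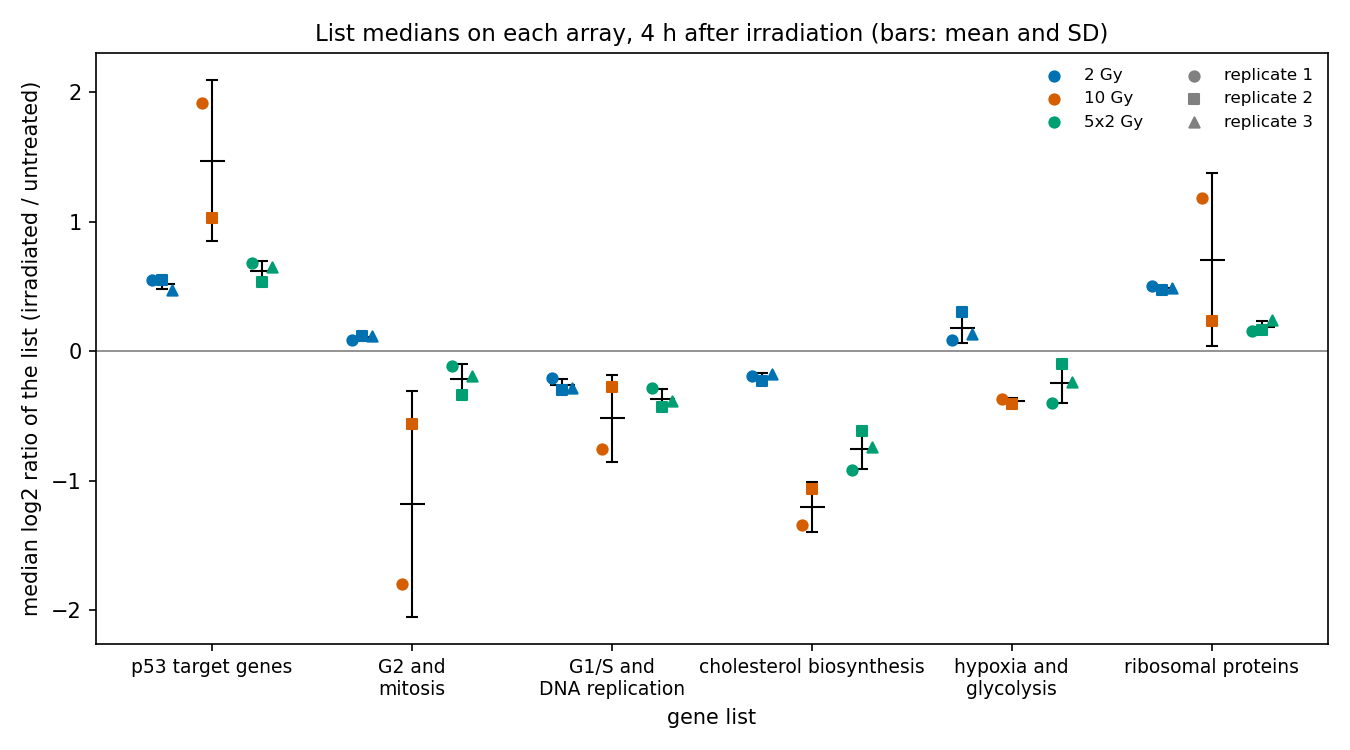
Median log2 ratio of irradiated over untreated cells (y axis) of 6 fixed gene lists (x axis) on each of the 8 arrays. Colours give the regimen, symbols the replicate, and black bars the mean and SD of a regimen. The p53 target list lies at 1.91 and 1.03 on the 10 Gy arrays and between 0.47 and 0.68 on the others, and the cholesterol biosynthesis list lies at -0.62 or below on every 10 Gy and 5x2 Gy array.

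In limma, 2357 genes were higher and 3134 lower after 5x2 Gy, 5491 in all, and 152 and 119 of them changed at least 2-fold. Without 5x2 Gy replicate 1, 2 or 3 the count was 3216, 3097 or 3010, and with slide as a random block it was 816. A slide block moved the medians to -0.87 for G2 and mitosis, -0.53 for G1/S and DNA replication, 0.58 for MHC class I presentation, 0.59 for ribosomal proteins, 0.32 for interferon response and 0.26 for the extracellular matrix, with their calls kept, and left cholesterol biosynthesis at -0.74. With slide as a block Gpt2 was at -0.33 (adjusted p = 0.073), Trib3 at -0.02 (adjusted p = 0.94) and the hypoxia and glycolysis list lost its call (adjusted p = 0.080) at a median of -0.26, as in the analysis without the block. With median centring, the calls of that list (median -0.19, adjusted p = 0.071), of the G2 and mitosis list (-0.17, adjusted p = 0.056), of the extracellular matrix list (0.12, adjusted p = 0.054) and of the interferon list (0.18, adjusted p = 0.065) ended with medians of the same sign. Calls also ended without 5x2 Gy replicate 2 for G2 and mitosis (-0.14, adjusted p = 0.15) and the extracellular matrix (0.05, adjusted p = 0.076), and without replicate 1 for hypoxia and glycolysis (-0.18, adjusted p = 0.080) and interferon (0.14, adjusted p = 0.052).

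Across genes, which are not independent replicates, the responses to the 3 regimens correlated. Pearson's r of the mean log2 ratios was 0.62 for 2 Gy and 10 Gy, 0.62 for 2 Gy and 5x2 Gy and 0.69 for 10 Gy and 5x2 Gy. Simulated unchanged groups gave r of 0.41, 0.50 and 0.41 under the assumption that arrays with 1 replicate number share untreated cells and 50% of their variance, which neither the labels nor the values show. The covariances were 0.0947, 0.0815 and 0.143, and the simulated ones were 0.00884, 0.00882 and 0.00889. The genes called higher in both numbered 687, 755 and 1082, against 150, 212 and 292 for independent lists, and those called lower in both 625, 726 and 1391, against 168, 249 and 496. In all, 1114 genes were called in each of the 3 comparisons, 564 of them higher and 541 lower in each, and 9 in mixed directions. The untreated cells and the dye orientation cannot be split between comparisons here. Slide was not part of the simulation. For arrays of 1 slide, limma gave a consensus correlation of 0.697 of what the regimen means leave over. That value depends on the 10 Gy arrays, the only replicates that lay on both slides. Part of the excess may come from the untreated cells, the dye orientation or the slide.

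Gene-specific dye bias cancels between regimens where it is the same on each array, which was not tested across the slides. The median signal of the irradiated channel was 266 to 409 on slide 1 and 163 to 208 on slide 2. Saturated probes of the untreated channel numbered 0 to 2 on slide 1 and 43 to 71 on slide 2. The higher single dose was compared with the lower one. After 10 Gy, 23 of 58 genes of G2 and mitosis, 13 of 25 of cholesterol synthesis and 10 of 36 of hypoxia and glycolysis were lower than after 2 Gy, and 7 of 41 p53 target genes were higher. Scd2 was lower by 2.39 on the log2 scale (difference -2.39 ± 0.23, 2 against 3 arrays, adjusted p = 0.012) and Fdps was at -1.79 ± 0.18 (adjusted p = 0.012). The kinetochore and spindle genes Cenpe (-2.10 ± 0.43), Cenpf (-2.07 ± 0.27) and Nusap1 (-2.05 ± 0.27) and Bnip3, a hypoxia-inducible mitophagy receptor (-1.87 ± 0.32), were lower. Crip2 (2.67 ± 0.45), Ak1 (1.72 ± 0.22), Robo3 (1.88 ± 0.38), Angptl4 (1.74 ± 0.38) and Fgf18 (1.69 ± 0.30) were higher, each at adjusted p = 0.047 or below.

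Of the 58 G2 and mitosis genes, 23 were lower after 10 Gy than after 2 Gy and none higher (51 and 1 adjusted over the list alone), with a median of -1.32 (adjusted p = 2.2e-27, and adjusted p = 0.31 with an estimated correlation). Of the 25 cholesterol biosynthesis genes, 13 were lower (21 adjusted over the list alone) and none higher, with a median of -0.99995 (adjusted p = 9.4e-16, and adjusted p = 0.17 with an estimated correlation). Of the 36 hypoxia and glycolysis genes, 10 were lower and 1 higher (22 and 1 adjusted over the list alone), with a median of -0.56 (adjusted p = 6.6e-11, and adjusted p = 0.31 with an estimated correlation). Slc16a3 (-1.43 ± 0.17), Slc2a1 (-1.44 ± 0.24) and the hypoxia-inducible demethylase Kdm3a (-1.09 ± 0.14) are examples. Of the 41 p53 target genes, 7 were higher and none lower (26 and 1 adjusted over the list alone), with a median of 0.86 (adjusted p = 7.1e-18, and adjusted p = 0.31 with an estimated correlation), among them the phosphatase Ppm1d (0.95 ± 0.15) and Ei24 (1.08 ± 0.18). In the fry test the calls of the G2 and mitosis and p53 target lists ended (adjusted p = 0.055 for each). Those of cholesterol biosynthesis (adjusted p = 0.0032) and hypoxia and glycolysis (adjusted p = 0.028) held there. Within slide 1, where 10 Gy replicate 1 alone stood against the 3 arrays of 2 Gy, the medians were -1.90 for G2 and mitosis, -1.25 for cholesterol biosynthesis, -0.60 for hypoxia and glycolysis and 1.32 for p53 targets. Without 10 Gy replicate 1 they were -0.69, -0.85, -0.61 and 0.46, which sets replicate 2 on slide 2 against slide 1. Each of these medians rests on 1 array of 10 Gy.

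In limma, 139 genes were higher and 204 lower after 10 Gy than after 2 Gy. With median centring these were 103 and 391, and with scaling between arrays 4 and 23. The count was 4298 with slide as a block, which leaves 10 Gy replicate 1 against 2 Gy, and 2897 with slide as a random block. It was 0 without any 1 of the 2 Gy arrays, 5, 4 and 4 without 5x2 Gy replicate 1, 2 or 3, 1496 without 10 Gy replicate 1 and 4298 without 10 Gy replicate 2, so it fell with any array of 2 Gy or 5x2 Gy left out, the latter being outside this comparison.

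The fractionated course was compared with its single fraction. After 5x2 Gy, 3 of 25 cholesterol synthesis genes and 3 of 36 hypoxia and glycolysis genes were lower than after 2 Gy, and 4 of 49 extracellular matrix genes were higher. Fdps was at -1.26 ± 0.16 (3 against 3 arrays, adjusted p = 0.026), the phosphomevalonate kinase Pmvk at -1.15 ± 0.15 (adjusted p = 0.024) and Slc16a3 at -1.18 ± 0.15 (adjusted p = 0.024). Dbi, an acyl-CoA binding protein (-1.37 ± 0.16), Cenpf (-1.31 ± 0.24), the kinase Rock1 (-1.52 ± 0.29) and Hnrnpa0 (-1.23 ± 0.14) were also lower. Mmp3, the metalloproteinase stromelysin, was higher by 1.86 ± 0.31 (3.62-fold, adjusted p = 0.037), as were Eif4ebp2 (1.67 ± 0.30), the copper carrier ceruloplasmin, Cp (1.29 ± 0.15), Ak1 (1.19 ± 0.20), Tgfbi (1.15 ± 0.19) and Sulf2 (0.99 ± 0.16).

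Of the 25 cholesterol biosynthesis genes, 3 were lower after 5x2 Gy than after 2 Gy (17 adjusted over the list alone) and none higher, with a median of -0.52 (adjusted p = 9.7e-07, and adjusted p = 0.49 with an estimated correlation). Of the 36 hypoxia and glycolysis genes, 3 were lower (15 adjusted over the list alone) and none higher, with a median of -0.51 (adjusted p = 1.4e-07, and adjusted p = 0.49 with an estimated correlation). These 3 were Slc16a3, Kdm3a (-0.97 ± 0.12) and Higd1a (-1.08 ± 0.13). With slide as a block, which joins the differences within the slides through the 10 Gy pair, both medians kept their sign (-0.84 and -0.38) and their calls. Of the 49 extracellular matrix and TGF-beta response genes, 4 were higher and none lower (7 and 1 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.00072, and adjusted p = 0.49 with an estimated correlation). Those 4 were Mmp3, Tgfbi, Thbs2 (0.97 ± 0.12) and Mmp10 (0.91 ± 0.15). Of the 58 G2 and mitosis genes, 1 was lower (11 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.00017, and adjusted p = 0.95 with an estimated correlation), and the median was -1.67 with slide as a block. The 41 p53 target genes had a median of 0.15, with 2 higher (2 adjusted over the list alone), an adjusted p = 0.046, and an adjusted p = 0.95 with an estimated correlation. That median was 0.97 with slide as a block and -0.00164 with median centring, where the call ended (adjusted p = 0.097). It also ended without 2 Gy replicate 1 (median 0.12, adjusted p = 0.11) and without 5x2 Gy replicate 1 or 3 (0.16 and 0.13, adjusted p = 0.092 and 0.063). None of the 77 ribosomal protein genes passed the test, with a median of -0.28 (adjusted p = 0.00047, and adjusted p = 0.95 with an estimated correlation), and this median was 0.58 with slide as a block and -0.67 with median centring. In the fry test the calls of G2 and mitosis, p53 targets, extracellular matrix and ribosomal proteins ended (adjusted p = 0.64, 0.77, 0.070 and 0.64). Those of cholesterol biosynthesis and hypoxia and glycolysis held there (adjusted p = 0.048 for each).

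In limma, 51 genes were higher and 124 lower after 5x2 Gy than after 2 Gy. With median centring these were 53 and 693, and the median of all genes moved to -0.13. The count was 2368 with slide as a block, 0 without any 1 of the 2 Gy or 5x2 Gy arrays and 4003 without either 10 Gy array. Under the slide block Mmp3 was at 0.32 (adjusted p = 0.32), Eif4ebp2 at 0.25 (adjusted p = 0.54) and Tgfbi at 1.05 (adjusted p = 0.052).

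The last comparison set the same total dose as 5 fractions against 1 dose. No single gene passed limma's threshold between 5x2 Gy and 10 Gy, and 2242 genes had an unadjusted p under 0.05. The 5 genes with the smallest p, all at adjusted p = 0.17, were Gm13777 (-1.20 ± 0.16), the proteasome subunit Psmb3 (-1.33 ± 0.19), Rnf157 (1.32 ± 0.19), Scd2 (1.46 ± 0.23) and Rpl15 (-1.31 ± 0.21). As a list, the 58 G2 and mitosis genes stood higher after 5x2 Gy than after 10 Gy, with a median of 0.93 (adjusted p = 1.2e-18, and adjusted p = 0.58 with an estimated correlation) and 36 of them higher adjusted over the list alone. The 41 p53 target genes stood lower, with a median of -0.68 (adjusted p = 5.8e-13, and adjusted p = 0.58 with an estimated correlation) and 17 of them lower adjusted over the list alone. The 25 cholesterol biosynthesis genes stood higher, with a median of 0.50 (adjusted p = 2.2e-06, and adjusted p = 0.58 with an estimated correlation) and 12 of them higher adjusted over the list alone. In the fry test the calls of these 3 lists ended, at adjusted p = 0.21, 0.18 and 0.060. Within slide 2, where 10 Gy replicate 2 alone stood against the 3 arrays of 5x2 Gy, their medians were 0.30, -0.27 and 0.35. The 77 ribosomal protein genes had a median of -0.49 (adjusted p = 3.1e-13, and adjusted p = 0.58 with an estimated correlation) and of -0.03 within slide 2, and with median centring it was -0.94, on a list with saturated spots in 61 of 77 members. The call of that list ended in the fry test too (adjusted p = 0.25). Without 10 Gy replicate 2 the count of genes was 5787, so the array chosen to stand for 10 Gy decides it. A test of any difference among the 3 regimens called 199 genes, 0 without any 1 of the 2 Gy or 5x2 Gy arrays, 3538 without 10 Gy replicate 1, 7405 without 10 Gy replicate 2 and 3645 with slide as a block.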

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

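The tests of slide, and the test whether 10 Gy replicate 2 is a 5x2 Gy sample, were chosen after the result was seen, and the others before.

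The genes tested have a symbol, so the 1596 probes above background without a symbol are outside the comparisons of the report. Tested apart against untreated cells, 251 of them passed the threshold after 2 Gy, 342 after 10 Gy and 659 after 5x2 Gy (15.7%, 21.4% and 41.3%, against 16.1%, 27.2% and 41.9% of the probes with a symbol). They stand here because they are a signal in data that the comparisons do not use, and no explanation of them was tested.

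A first pattern is that 1105 genes were called in the same direction against untreated cells in all 3 regimens. Bias of single probes is argued against only for the direction of the 190 such genes with other probes of near brightness above background. Of these, 93.7% had the same sign on those probes, against 73.8% of 1791 among all genes tested. With other kept probes of any brightness, the same sign was found for 87.1%, 84.7% and 71.2% of the genes called after 2 Gy, 10 Gy and 5x2 Gy. Genes without another probe could not be tested. A dye bias of whole transcripts, which no exchange of dyes removes, stays open: 26.4% of these genes differed among regimens at an unadjusted p under 0.05, against 27.1% of all genes. A pure dye bias, equal on all arrays, would leave about 5%, and a response of every regimen at 1 size would too. Shared untreated cells stay open as well, and a shared response to X-rays, the biological explanation that the groups give, could not be separated from these.

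The 2 arrays of 10 Gy differ from each other, with G2 and mitosis medians of -1.80 and -0.56. Another untreated sample on 1 of them is argued against for that list, since the untreated channel gave 17.2% of the shift of the ratio. It stays open for the ribosomal proteins, where the ratio moved by -0.84, the untreated channel by 1.29 and the irradiated channel by 0.06, on a list with saturated spots in 61 of 77 members. That replicate 2 is a sample of 5x2 Gy goes with its correlation over genes with those arrays (0.748 to 0.854, against 0.427 with replicate 1). The 5x2 Gy arrays correlated with each other at 0.829 to 0.886. They share the slide of replicate 2, though replicate 1 correlated with the 2 Gy arrays of its slide at only 0.390 to 0.511. The G2 and mitosis and p53 target medians of replicate 2 lay outside the range of the 5x2 Gy arrays by 1.01 and 2.41 times its width. That range rests on 3 arrays, the bound of 1 was set after the result was seen, and the first lay only just past it. The question whether replicate 2 is a 5x2 Gy sample therefore stays open. Slide stays open: over genes, which are not independent, replicate 2 minus replicate 1 correlated at r = 0.312 with 5x2 Gy minus 2 Gy, between the bounds set for and against it, and no biological explanation was tested, since the labels give these arrays 1 treatment.

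The cholesterol biosynthesis and the hypoxia and glycolysis lists were lower after 10 Gy and after 5x2 Gy than after 2 Gy. For 10 Gy, replicate 1, on the slide of the 2 Gy arrays, lay below all 3 of them by 1.11 for cholesterol biosynthesis and 0.459 for hypoxia and glycolysis. That argues against slide as the whole cause for this 1 array only, which correlated with replicate 2 at r = 0.427. It does not decide for 10 Gy as a regimen. For 5x2 Gy, a trend with probe brightness was not decided, since loess had already removed such trends from each array. After loess, 0 of 10000 random lists of like brightness had a median as low for either list in 5x2 Gy against 2 Gy. Slide cannot be told apart from the regimen there, because the 10 Gy pair that links the slides differs in its response, though from replicate 1 to replicate 2 the median of the gene differences was 0.135 for cholesterol biosynthesis and 0.0794 for hypoxia and glycolysis, while the median of the latter list went from -0.37 to -0.40. A response to the regimen stays open and was not tested apart from these, and total dose alone would not separate 5x2 Gy from 10 Gy, where the cholesterol biosynthesis list had a median difference of 0.50 (0.35 within slide 2).

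Of the 10 splits of the 6 arrays of 2 Gy and 5x2 Gy into 3 and 3, the real one gave 175 genes and 1 of 10 gave as many, the highest of the others being 0. That is too few splits for a share under 0.05, the real split is also the split by slide, and with slide as a block the count was 2368.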

How the results depend on the processing

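Slide as a fixed block for the gene lists, slide as a random block and leaving out spots with an ImaGene flag were chosen after the result was seen. The Agilent LogRatio alternative was not run, since the files hold no such column. Array weights were 0.189 for both 10 Gy arrays and between 0.81 and 4.78 for the others. The cause of a change in a count was not tested unless given.

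For 2 Gy against untreated cells (2272 genes) the count was 3609 with median centring, 4126 with scaling between arrays, 7279 with array weights, 4461 with slide as a fixed block (1418 shared), 21 with it as a random block, 4818 with only the 2 Gy arrays and 781 with at least 1.5-fold. Leaving out 1 array gave 408 to 5382. For 10 Gy (3783) it was 222 with array weights, 6520 and 1466 with slide as a fixed and a random block, 280 with only the 10 Gy arrays and 2261 with at least 1.5-fold, and 2912 to 6080 leaving out 1 array. For 5x2 Gy (5491) it was 8443 with no filter on dim probes, 8386 for every probe on its own, which tests more probes, 8952 with array weights, 816 with slide as a random block and 2024 with at least 1.5-fold, and 3010 to 7981 leaving out 1 array.

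For 10 Gy against 2 Gy (343) the count was 27 with scaling between arrays, 2 with array weights, 4298 and 2897 with slide as a fixed and a random block (343 shared with each), 0 with only the groups compared and 0 to 4298 leaving out 1 array. For 5x2 Gy against 2 Gy (175) it was 746 with median centring, 56 with scaling between arrays, 401 for every probe on its own, 74 with eBayes with trend and robust, 6011 with array weights, 2368 with slide as a fixed block (85 shared), 4003 with only the groups compared and 0 to 4003 leaving out 1 array. For 5x2 Gy against 10 Gy (0 in limma, 2242 at an unadjusted p under 0.05) it was 1 without flagged spots and 0 to 5787 leaving out 1 array. For any difference among the 3 regimens (199) it was 523 with median centring, 20 with scaling between arrays, 14 with trend and robust, 4861 with array weights, 3645 and 1956 with slide as a fixed and a random block, 123 without flagged spots and 0 to 7405 leaving out 1 array. Where 1 array of 10 Gy is left, it is assumed to vary like the other regimens, and leaving out either one takes the difference within that pair out of the spread.

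With a replicate block the counts were 1423 for 2 Gy and 2278 for 10 Gy against untreated cells and 0 for 10 Gy against 2 Gy, for 5x2 Gy against 2 Gy and for any difference among the regimens. Whether the replicate numbers pair the arrays was not decided. The deviations of same-numbered arrays from their regimen's mean correlated at r = -0.24 to 0.11 over genes (7 pairs), and those of other arrays at -0.11 to 0.24 (14 pairs). The ends of both ranges come from pairs with a 10 Gy array. The deviations of the 2 arrays of 10 Gy mirror each other, which forces these r to be equal with opposite sign.

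Of the 60 calls of lists, 0 held with an estimated correlation, and fry called 30 (22 shared), a test of another question. The other alternatives gave 41 to 67, that range being that of leaving out 1 array. Without 10 Gy replicate 1 the direction of the list test reversed for 10 Gy against 2 Gy for homologous recombination (median -0.022, leaving out 1 array -0.65 to -0.022), G1/S and DNA replication (0.023, -0.49 to 0.023), MHC class I presentation (-0.10, -0.10 to 0.38), oxidative stress (-0.22, -0.22 to 0.43) and ribosomal proteins (-0.23, -0.23 to 0.59). Under slide as a fixed block the ribosomal proteins reversed to 0.58 for 5x2 Gy against 2 Gy. With that block, and to the same values without 10 Gy replicate 1, the direction reversed for 5x2 Gy against 10 Gy for homologous recombination (-0.13, leaving out 1 array -0.13 to 0.59), MHC class I presentation (0.037, -0.60 to 0.037), immediate early genes (0.087, -0.69 to 0.087), integrated stress response (0.078, -0.34 to 0.078) and oxidative stress (0.008025, -0.77 to 0.008025). In these, 10 Gy replicate 2 alone stands for the pair. Kept under all 13 alternatives other than an estimated correlation were, against untreated cells, p53 targets, G1/S and cholesterol biosynthesis after 10 Gy and 5x2 Gy and G2 and mitosis after 10 Gy, and, between regimens, cholesterol biosynthesis and hypoxia and glycolysis lower after 10 Gy and after 5x2 Gy than after 2 Gy. The ribosomal proteins after 10 Gy kept their call too, but 61 of the 77 had a saturated spot, so this says nothing about stability.

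Of 634 values of named genes, the sign reversed for Vash2 after 2 Gy with the stricter filter (0.46), which leaves its other probe, and for Srxn1 after 10 Gy with the mean of its probes (0.10). Slide as a fixed block left 526 the same, 36 weaker and 72 stronger, and median centring 556, 28 and 50. Fewer stayed the same with slide as a random block (430, with 152 weaker and 52 stronger) and with array weights (438, 105 and 91). Signal over background limits the genes tested, and the number of arrays limits the precision.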

Other observations

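Slide as a block was chosen for the gene lists after the result was seen.

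The lists not described in the report, with median log2 ratios after 2 Gy, 10 Gy and 5x2 Gy, were non-homologous end joining (0.04, -0.17 and -0.01), base and nucleotide excision and mismatch repair (0.02, -0.18 and -0.15), immune ligands and checkpoints (0.16, 0.13 and 0.26), NF-kB targets and cytokines (0.12, 0.19 and -0.06), immediate early genes (-0.11, 0.23 and -0.13), integrated stress response (-0.05, 0.05 and -0.12) and heat shock proteins (-0.13, -0.01 and 0.02). None of these passed the camera list test against untreated cells in the analysis without a slide block. In the fry test, immune ligands and checkpoints passed upward after 2 Gy, 10 Gy and 5x2 Gy (adjusted p = 0.0015, 0.00028 and 0.0027). Excision and mismatch repair passed downward in that test after 10 Gy and 5x2 Gy (adjusted p = 0.018 and 0.020). Between regimens, immediate early genes passed for 10 Gy against 2 Gy (0.21, adjusted p = 0.0056, and adjusted p = 0.47 with an estimated correlation) and for 5x2 Gy against 10 Gy (-0.36). Their median was 0.55 in 10 Gy replicate 1 and -0.21 in replicate 2. Without 10 Gy replicate 1 the medians of these 2 comparisons were -0.04 and 0.09, so both calls rest on that array. Heat shock proteins passed for 10 Gy against 2 Gy (0.07) and the integrated stress response for 5x2 Gy against 10 Gy (-0.18). In the fry test each of these calls between regimens ended. With slide as a block, immediate early genes passed after 2 Gy (-0.51, adjusted p = 4.4e-05), 10 Gy (0.23, adjusted p = 0.040) and 5x2 Gy (0.35, adjusted p = 0.0048), the integrated stress response after 2 Gy (-0.17, adjusted p = 0.0020), and NF-kB targets (0.20, adjusted p = 0.025) and excision and mismatch repair (-0.27, adjusted p = 0.027) after 5x2 Gy. These values after 2 Gy and 5x2 Gy take in the difference between the 10 Gy arrays and are no response measured on their own arrays. Without the block, the immediate early list had medians of -0.07, -0.16 and -0.09 on the 2 Gy arrays. On the 5x2 Gy arrays its medians were -0.18, -0.08 and -0.13, of the same sign. With median centring, the integrated stress response (0.30, adjusted p = 0.022) and heat shock proteins (0.14, adjusted p = 0.031) passed after 10 Gy. The mean and the test differed in sign from the median for excision and mismatch repair after 2 Gy (mean -0.04), NF-kB targets after 5x2 Gy (mean 0.05) and heat shock proteins after 10 Gy (mean 0.14) and 5x2 Gy (mean -0.05).

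Oxidative stress and NRF2 targets were at 0.06, 0.41 and 0.05 and passed after 10 Gy (adjusted p = 0.00098, and adjusted p = 0.49 with an estimated correlation, and 0.07 with adjusted p = 0.80 without 10 Gy replicate 1). They also passed after 2 Gy with median centring (0.57, adjusted p = 0.020) and after 5x2 Gy with slide as a block (0.36, adjusted p = 1.4e-06). Their call after 10 Gy ended in the fry test (adjusted p = 0.13). Apoptosis regulators were at 0.07, 0.14 and 0.18 and passed after 2 Gy (adjusted p = 0.028, and adjusted p = 0.46 with an estimated correlation) and 10 Gy (adjusted p = 0.024, and adjusted p = 0.26 with an estimated correlation). In the fry test they also passed upward after 5x2 Gy (adjusted p = 0.0076). The call after 2 Gy ended with slide as a block, at a higher median of 0.22 (adjusted p = 0.050307), and the call after 10 Gy without 10 Gy replicate 2, at 0.09 (adjusted p = 0.11). The hypoxia and glycolysis list passed after 2 Gy as well, at 0.18 (adjusted p = 0.023, and adjusted p = 0.71 with an estimated correlation), but not with slide as a block, where the median stayed at 0.18 (adjusted p = 0.33), or without 2 Gy replicate 2, where it was 0.12 (adjusted p = 0.16). That call also ended in the fry test (adjusted p = 0.15). The homologous recombination list, described in the report after 10 Gy, was at -0.13 after 2 Gy (adjusted p = 0.13) and at -0.24 after 5x2 Gy (adjusted p = 0.048, and adjusted p = 0.83 with an estimated correlation). Its call after 5x2 Gy ended with median centring (-0.21, adjusted p = 0.054) and without 2 Gy replicate 1 or 2 (adjusted p = 0.052 and 0.053, both at -0.24) or 5x2 Gy replicate 2 or 3 (-0.26 and -0.23, adjusted p = 0.076 and 0.067). The call also ended with replicate as a block (-0.24, adjusted p = 0.051) and in the fry test (adjusted p = 0.12), and the median was -0.55 with slide as a block. The cause of these changes was not tested. Histones of replication were at -0.22 after 10 Gy (adjusted p = 0.048, and adjusted p = 0.56 with an estimated correlation) and lost this call with median centring (0.01, adjusted p = 0.79), without 10 Gy replicate 1 (-0.04, adjusted p = 0.46), without 2 Gy replicate 3 (-0.22, adjusted p = 0.054), with replicate as a block (-0.20, adjusted p = 0.091) and in the fry test (adjusted p = 0.12). After 2 Gy their median was -0.02 with a mean of 0.08, and after 5x2 Gy 0.13 with a mean of -0.000277, neither past the list test.

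Of 29 leukocyte markers 28 were on the array and 13 were above the filter, with medians of 0.02, -0.01 and 0.02, and of 17 fibroblast and endothelial markers 9 were, with medians of 0.36, -0.04 and 0.06. Neither list passed the camera test, and after 10 Gy the leukocyte list had a mean of 0.23 and the fibroblast and endothelial list a test direction opposite to its median. In the fry test the fibroblast and endothelial list passed upward after 5x2 Gy (adjusted p = 0.049). The median log2 intensity of the leukocyte markers was 8.31, against 9.92 for all genes.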
